A study of Mus musculus with 24 samples.

How the data were processed

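Total RNA from 24 mouse livers was extracted with Trizol by the authors, and 300 ng per sample was labelled with the Affymetrix WT PLUS kit. The labels give a genotype (Ppara wild type or knockout) and an infection status for each array, and each array is 1 biological replicate. Arrays were grouped by these labels into 4 groups of 6. The deposited values were in log2, 1 value per transcript-level probe set, made by the authors with RMA (background correction, quantile normalization and summarization) in the R package oligo, whose version is not given. Values ran from 0.574 to 13.26. Filters are not stated. The background correction and summarization could not be varied, since only the summarized values were used here. Array data have no read depth, and the number of arrays limits the precision.

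The table held 41345 probe sets, of which 25335 had a gene annotation. The 23521 probe sets with 1 gene symbol were used for named genes, and 1814 with several symbols and 16010 without annotation were left out of the gene tests. For each of 22180 genes the probe set with the highest mean over all arrays was kept (1082 genes had over 1 probe set). Entrez identifiers of 23328 probe sets were found in the RefSeq table of the mouse assembly GRCm38.p6, which was used for names and for the gene order around Ppara. Probe sets of close paralogs, such as those of the Cyp, Sult, Acot and Mup families, may share signal.

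Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 20 residual and 5.42 prior degrees of freedom), with all 4 groups in 1 fit. The 5 comparisons were infection in wild type, infection in knockout, knockout minus wild type without infection, the same with infection, and the interaction, the infection effect in knockout minus that in wild type. Tests were two-sided, p was adjusted by the Benjamini-Hochberg method over all genes within a comparison, and the threshold was 0.05. The 38 gene lists, the rule for named genes, the comparisons and the other settings listed below, but for those said to be added, were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, adjusted over lists within a comparison, and again with an estimated correlation and with fry. Of the 31 measured PPARα target genes 16 were also in another list. Named genes were the 8 with the greatest rise and the 8 with the greatest fall in each comparison, among genes past the threshold whose groups did not overlap (predicted genes, receptor families and small RNA genes skipped, and no overlap rule for the interaction), up to 3 members of each list described and 1 that moved the other way, and a set of genes named beforehand.

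The alternatives were the replicate number as a block, quantile normalization again, arrays centred on their median, removal of dim genes (mean under 3.18), the mean of a gene's probe sets or the probe set with the lowest mean, eBayes with trend and robust, array weights, a fit of the compared groups alone, a threshold of 0.01, a test against a 1.2-fold change, and each array left out in turn. Knockout infected replicates 4 to 6 alone and 1 to 3 alone were added after the arrays had been seen. The fit was tested on simulated data: of 200 genes changed 2-fold, 91% to 94.5% were called in the 2-group comparisons and 79% in the interaction. Of 200 changed 1.5-fold, 63% to 68% and 22.5% were called. The simulated noise was independent, with 1 spread per gene in all groups. These shares therefore do not cover spread that differs between groups or the separate sets of knockout infected arrays.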

Results

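Liver RNA of 24 mice was measured on 24 Affymetrix whole-transcript arrays, 1 mouse per array. The mice were wild type or lacked Ppara in the whole body. Ppara encodes the nuclear receptor PPARα, which induces genes of fatty acid oxidation and ketone body production in the fasted liver. Mice of each genotype were left uninfected or were infected with Escherichia coli to induce sepsis and killed 16 hours later, which gave 4 groups of 6 arrays. Values were log2 intensities of 41345 probe sets, and array medians lay between 4.126 and 4.262. One probe set was kept for each of 22180 named genes. The comparisons ask how the liver responded to infection in each genotype, how the genotypes differed with and without infection, and whether the response differed between genotypes. Errors of log2 differences are standard errors from limma with n = 6 per group, and every gene said to have risen, fallen or changed passed a Benjamini-Hochberg adjusted p of 0.05.

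The first principal component, with 46.5% of the variance, separated infected from uninfected arrays, and the second, with 10.4%, separated 3 knockout infected arrays from the rest. Knockout infected replicates 1 to 3 lay at -73.3, -67.7 and -69 on the second component, and replicates 4 to 6 at 19.9, 19.7 and 22.3. Wild-type infected replicates 1 to 3 lay at 25, 18.8 and 16 and replicates 4 to 6 at -8.03, 1.36 and 6.28, a smaller separation by the same numbers with the opposite sign. Replicates 1 to 3 correlated with replicates 4 to 6 at 0.951 to 0.960 over all probe sets, against 0.981 to 0.984 within each trio. Interferon-stimulated genes averaged 0.433 to 0.455 above the wild-type controls (mean log2) in replicates 1 to 3, 2.38 to 2.52 in replicates 4 to 6 and 2 to 2.51 in wild-type infected arrays (2.51, 2.3 and 2.44 in replicates 1 to 3 and 2, 2.14 and 2.14 in replicates 4 to 6). Acute phase genes averaged 1.5 to 1.59 above the wild-type controls in replicates 1 to 3 and 1.34 to 1.42 in replicates 4 to 6. Monocyte markers averaged 1.19 to 1.57 in replicates 1 to 3 and 0.439 to 0.776 in replicates 4 to 6, and cholangiocyte markers 0.0541 to 0.141 and 0.557 to 0.652. No label divides the 6 mice of either infected group, and no arrays held identical values (highest correlation 0.987).

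**Figure D1:**
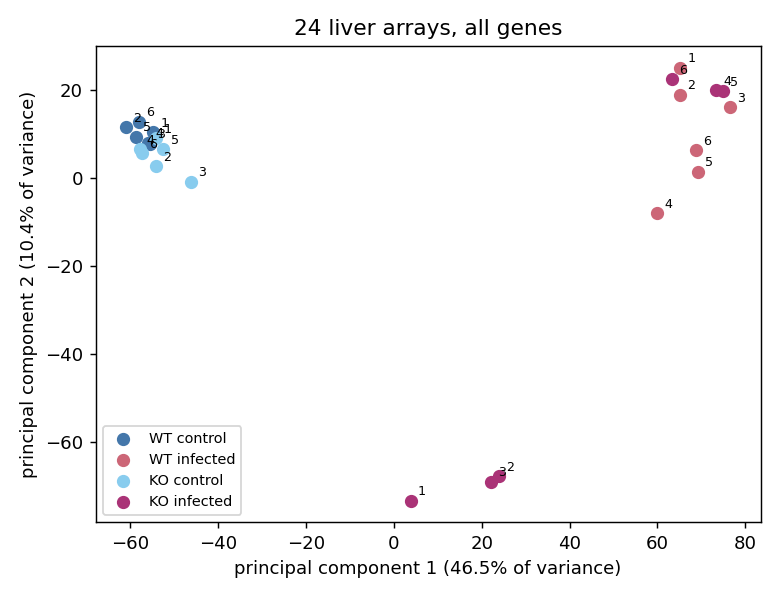
Positions of the 24 liver arrays on the first 2 principal components of all probe sets (axes in component units with the percent of variance, colours for the 4 groups, numbers for replicates). Uninfected arrays of both genotypes lie together at the left, and knockout infected replicates 1 to 3 lie apart at the bottom, between -73.3 and -67.7 on the second component.

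The probe set of Ppara, the targeted gene, read 7.98 ± 0.16 (log2 intensity, SD, n = 6) in wild-type controls and 8.01 ± 0.13 in knockout controls, so it did not separate the uninfected genotypes. A probe set can lie outside the deleted part of a gene, and its level then checks nothing about the deletion. In infected mice it read 7.92 ± 0.13 in wild type and 6.98 ± 0.38 in knockout, a fall of 1.91-fold between infected genotypes (log2 -0.94 ± 0.13, adjusted p = 2.46e-05). Cyp4a14, a fatty acid omega-hydroxylase and classical PPARα target, separated the genotypes instead, at 10.41 ± 0.44 and 9.51 ± 1.23 in uninfected and infected wild-type mice and 4.82 ± 0.98 and 4.16 ± 0.93 in knockout mice. Vnn1, the pantetheinase vanin-1 and another PPARα target, read 7.68 ± 0.30 and 7.90 ± 0.51 in wild type and 3.77 ± 0.36 and 3.63 ± 0.34 in knockout. All 12 knockout arrays lay below all 12 wild-type arrays for both genes.

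**Figure D2:**
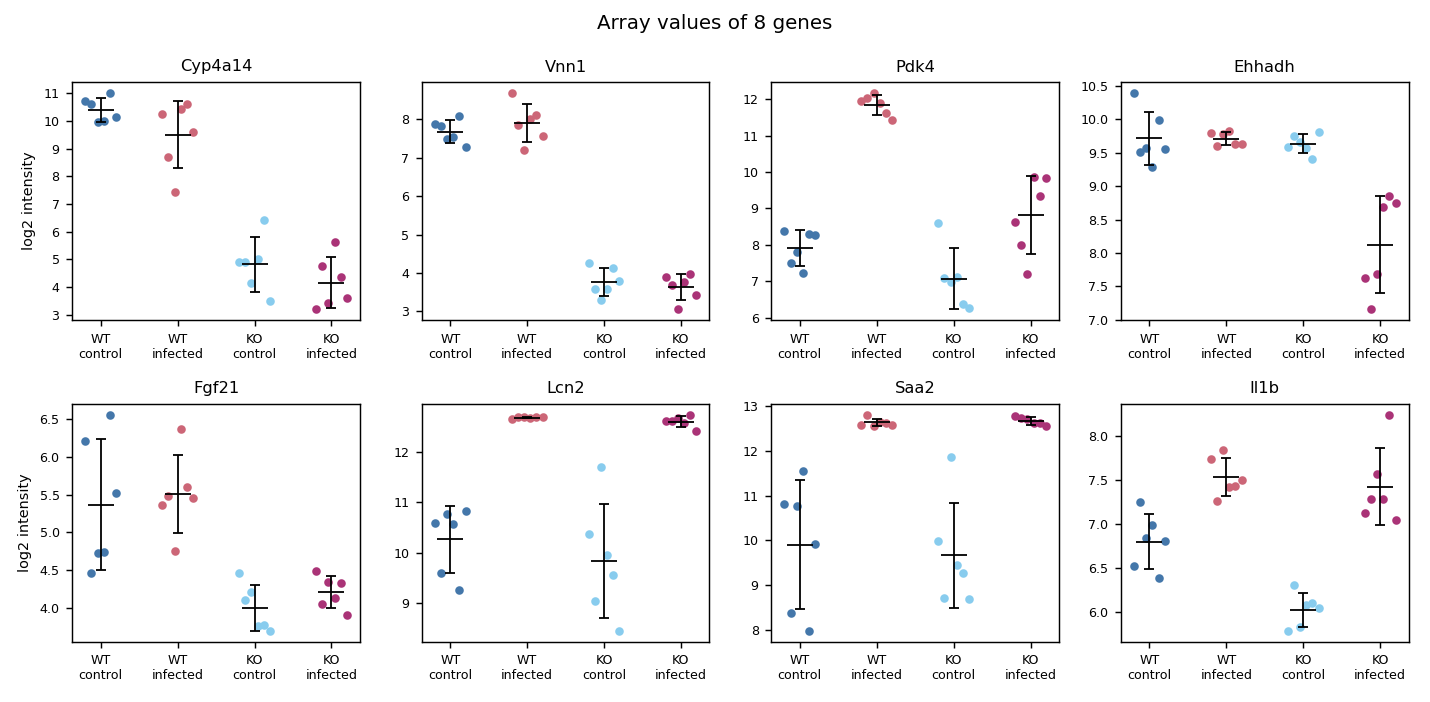
Log2 intensity of 8 genes on each array, by group; points are arrays, bars the group mean and SD (n = 6). Cyp4a14 and Vnn1 are lower in both knockout groups, Pdk4 rises with infection to a group mean of 11.85 in wild type and 8.82 in knockout, and Lcn2 and Saa2 of infected mice lie near the top of the scale.

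Infection in wild-type mice raised inflammatory genes and lowered genes of bile acid, cholesterol and fatty acid synthesis. The list calls of the lowered groups were lost with an estimated correlation (adjusted p = 0.0737, 0.0814 and 0.0682). The chemokine genes Ccl2 and Ccl3 rose 32.6-fold (log2 5.02 ± 0.26) and 28.8-fold (4.85 ± 0.26), and Cxcl10, an interferon-induced chemokine, rose 31.3-fold (4.97 ± 0.53). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell 18.0-fold (-4.17 ± 0.48), and G6pc, the catalytic subunit of glucose-6-phosphatase, fell 20.2-fold (-4.34 ± 0.58). Pdk4, a PPARα target that restrains pyruvate oxidation, rose 15.3-fold (3.94 ± 0.38). Of 22180 genes, 4340 were higher and 5025 lower, 1026 and 1577 of them by 2-fold or more, and 12815 did not pass.

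Other genes with the greatest rise were Selp (29.4-fold), which encodes P-selectin, the collagenase gene Mmp13 (27.5-fold), Acod1 (27.3-fold), whose enzyme makes itaconate, the lipopolysaccharide co-receptor Cd14 (26.3-fold) and the transporter Slc10a6 (24.8-fold). Those with the greatest fall also included Hykk (22.9-fold), Keg1 (18.1-fold), Ppp1r3c (17.8-fold), which encodes a glycogen-targeting phosphatase subunit, Hjv (15.6-fold), a co-receptor needed for hepcidin expression, Coq8a (log2 -3.73) and Sult3a2 (13-fold).

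Inflammatory lists rose in wild-type mice. All 28 measured acute phase genes rose and 0 fell, 28 and 0 also adjusted over the list alone (camera adjusted p = 1.94e-14, adjusted p = 0.0544 with an estimated correlation), among them Cd14, Saa3 (19.0-fold) and Il1rn (11.3-fold), the interleukin-1 receptor antagonist. Saa2 rose 6.70-fold, Lcn2 5.36-fold and Hamp, which encodes hepcidin, 1.39-fold, while Alb, the albumin gene, differed by -0.05 ± 0.06 (adjusted p = 0.566). Lcn2 and Saa2 of infected mice and Alb lay near the highest value in the table, 13.26, where differences can be compressed. Of 27 cytokine and chemokine genes 23 rose, 0 fell and 4 did not pass, the counts adjusted over the list alone being 23 and 0 (camera adjusted p = 1.85e-14). Cxcl1 rose 15.2-fold, Tnf 5.2-fold, Il6 4.53-fold and Il1b 1.66-fold. Of 25 NF-κB feedback and inflammasome genes 23 rose, 0 fell and 2 did not pass, with 23 and 0 adjusted over the list alone (camera adjusted p = 4.63e-19). Irak3 and Tnfaip3, negative regulators of Toll-like receptor and NF-κB signalling, rose 22.4-fold and 20.8-fold. Interferon-stimulated genes rose in 24 of 26 cases with 0 lower and 2 not past, and 25 and 0 adjusted over the list alone (camera adjusted p = 4.28e-13, adjusted p = 0.23 with an estimated correlation). Gbp5 rose 22.6-fold, the antiviral GTPase gene Mx1 20.1-fold and Rsad2 13.2-fold.

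Stress lists moved too. Glucocorticoid-induced genes rose in 15 of 18 cases, with 1 lower and 2 not past, and 15 and 2 adjusted over the list alone (camera adjusted p = 8.29e-08). Sult1e1 rose 11.7-fold, the clock gene Per1 8.09-fold and the cell cycle inhibitor gene Cdkn1a 7.28-fold, and Tsc22d3, itself a glucocorticoid-induced gene, fell 1.75-fold. Of 23 unfolded protein response genes 13 rose, 2 fell and 8 did not pass, with 13 and 2 adjusted over the list alone (camera adjusted p = 0.000361, adjusted p = 0.245 with an estimated correlation). Chac1, a glutathione-degrading enzyme gene, rose 11.2-fold, Atf3 6.07-fold and Manf 3.81-fold, and Sel1l fell 1.85-fold. Oxidative stress genes split into 7 higher, 5 lower and 3 not past of 15, with 7 and 5 adjusted over the list alone (camera adjusted p = 0.268). Heme oxygenase Hmox1 rose 6.90-fold, the cystine transporter gene Slc7a11 5.14-fold and the superoxide dismutase gene Sod2 3.26-fold, and Osgin1 fell 2.09-fold.

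Lipid synthesis lists fell in wild-type mice. Of 19 genes of cholesterol synthesis and uptake 18 fell, 0 rose and 1 did not pass, with 18 and 0 adjusted over the list alone (camera adjusted p = 7.49e-11, adjusted p = 0.0814 with an estimated correlation). Hmgcs1 fell 9.02-fold, Lss 5.08-fold and Insig1 4.56-fold. Of 16 lipogenesis genes 14 fell, 0 rose and 2 did not pass, with 14 and 0 adjusted over the list alone (camera adjusted p = 3.9e-06, adjusted p = 0.0682 with an estimated correlation), including Gpam (6.58-fold), the acetyl-CoA carboxylase gene Acaca (4.08-fold) and Pnpla3 (3.83-fold). Bile acid genes fell in 12 of 17 cases, with 0 higher and 5 not past, and 13 lower adjusted over the list alone (camera adjusted p = 5.31e-06, adjusted p = 0.0737 with an estimated correlation). Abcb11, the bile salt export pump gene, fell 8.02-fold and Hsd3b7 6.13-fold. Of 27 xenobiotic genes 15 fell, 0 rose and 12 did not pass, with 17 lower adjusted over the list alone (camera adjusted p = 0.000595, adjusted p = 0.377 with an estimated correlation). Cyp3a25 fell 7.66-fold, Cyp2b10 3.33-fold and Nr1i3, the xenobiotic receptor CAR, 7.52-fold. Of 21 liver nuclear receptors and coregulators 12 fell, 2 rose and 7 did not pass, with 12 and 2 adjusted over the list alone (camera adjusted p = 0.000177). Nr0b2 fell 5.86-fold and the thyroid hormone receptor gene Thrb 3.87-fold, while Cebpb, a transcription factor of the acute phase response, rose 4.59-fold.

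Fatty acid and energy genes moved in both directions in wild-type mice. PPARα target genes split into 8 higher, 6 lower and 17 not past of 31, with 8 and 6 adjusted over the list alone (camera adjusted p = 0.716, median log2 -0.23 and mean 0.15). Besides Pdk4, Angptl4, an inhibitor of lipoprotein lipase, rose 3.59-fold, the lipid droplet gene Cidec 6.66-fold and Cpt1a, the gate of mitochondrial fatty acid import, 1.52-fold, and the lipase gene Mgll fell 2.87-fold. Fgf21, a fasting hormone (0.14 ± 0.28, adjusted p = 0.737), Ehhadh (-0.00 ± 0.22, adjusted p = 0.991), Acot1 (-0.51 ± 0.34, adjusted p = 0.238) and Pck1 (0.05 ± 0.12, adjusted p = 0.758) did not pass. Of 18 mitochondrial fatty acid oxidation genes 10 fell, 3 rose and 5 did not pass, with 12 and 3 adjusted over the list alone (camera adjusted p = 0.0495, adjusted p = 0.377 with an estimated correlation), Acads by 1.63-fold, while Eci2 rose 1.68-fold. Of 19 peroxisomal genes 11 fell, 1 rose and 7 did not pass, with 12 and 1 adjusted over the list alone (camera adjusted p = 0.000844, adjusted p = 0.138 with an estimated correlation). Abcd2 fell 8.52-fold, Crot 2.52-fold, and Acaa1a rose 1.42-fold. Amino acid catabolism and urea cycle genes fell in 19 of 25 cases, with 3 higher, 3 not past and 19 and 5 adjusted over the list alone (camera adjusted p = 9.44e-05, adjusted p = 0.23 with an estimated correlation). Hal, which breaks down histidine, fell 6.63-fold and Kynu 5.81-fold. Of 24 oxidative phosphorylation genes 11 fell, 0 rose and 13 did not pass, with 12 lower adjusted over the list alone (camera adjusted p = 0.00154, adjusted p = 0.379 with an estimated correlation). Tricarboxylic acid cycle genes fell in 8 of 17 cases with 1 higher and 8 not past, 8 and 1 adjusted over the list alone (camera adjusted p = 0.0304, adjusted p = 0.245 with an estimated correlation). Glycolysis genes rose in 9 of 16 cases with 4 lower and 3 not past, 9 and 5 adjusted over the list alone (camera adjusted p = 0.058), with the regulator gene Pfkfb3 up 11.5-fold and Hk2 3.59-fold.

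Markers of other cell types moved with infection in wild type. Neutrophil markers rose in 18 of 20 cases with 0 lower and 2 not past, 19 and 0 adjusted over the list alone (camera adjusted p = 3.1e-10, adjusted p = 0.0881 with an estimated correlation), Ngp by 7.37-fold and S100a9 by 6.77-fold. Monocyte markers rose in 6 of 12 cases with 1 lower and 5 not past, 6 and 1 adjusted over the list alone (camera adjusted p = 0.0439, adjusted p = 0.332 with an estimated correlation), Chil3 by 3.98-fold. Liver endothelial markers fell in 14 of 16 cases with 2 higher, 14 and 2 adjusted over the list alone (camera adjusted p = 3.6e-07, adjusted p = 0.04 with an estimated correlation). Kdr, the main receptor for vascular endothelial growth factor, fell 9.98-fold, and Lyve1 rose 5.84-fold. Kupffer cell markers fell in 10 of 16 cases with 2 higher and 4 not past, 10 and 2 adjusted over the list alone (camera adjusted p = 0.00119, adjusted p = 0.292 with an estimated correlation). The iron exporter gene Slc40a1 fell 12.5-fold and Cd163 2.69-fold, and Marco rose 3.57-fold. Cell cycle genes fell in 13 of 22 cases with 3 higher and 6 not past, 13 and 3 adjusted over the list alone (camera adjusted p = 0.0239, adjusted p = 0.377 with an estimated correlation), Ccnb2 by 3.37-fold. Of the 9365 called genes 46.3% were higher, and with each array centred on its median 35.7% of 9044 were. Against a 1.2-fold change as the null, 2116 genes were higher and 3194 lower.

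**Figure D3:**
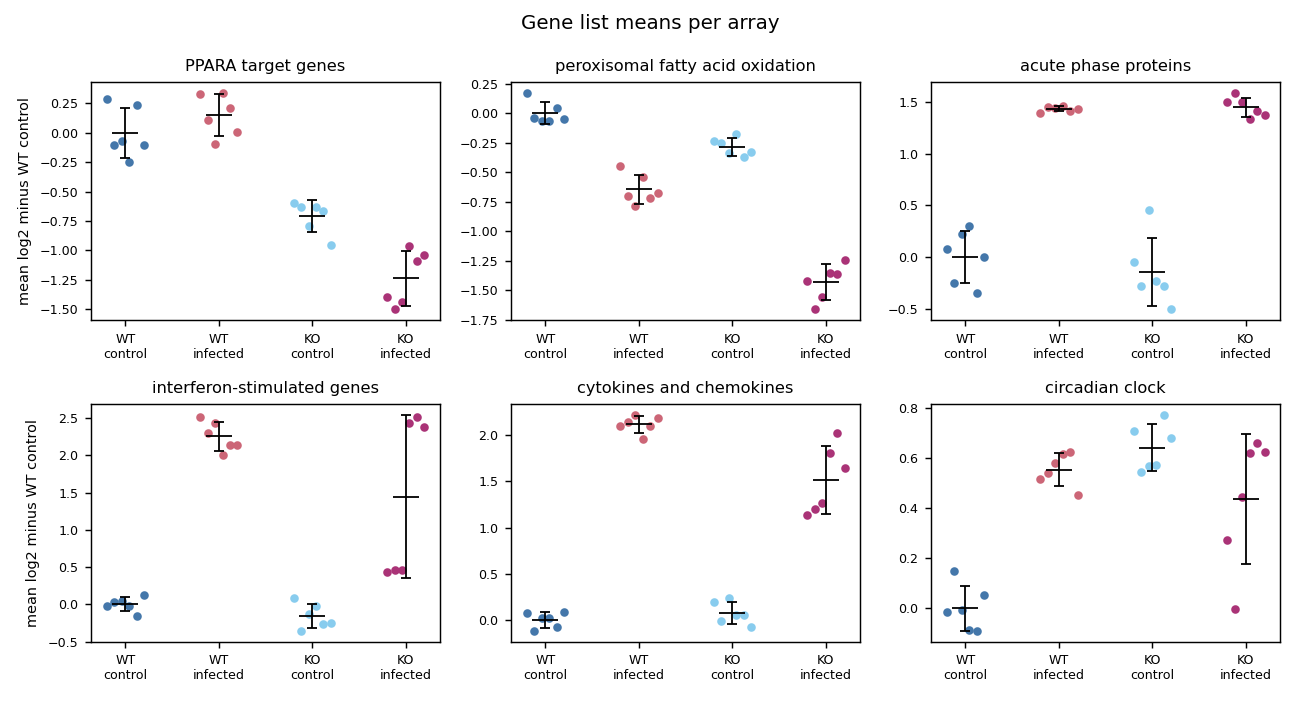
Mean log2 value of 6 gene lists on each array, relative to the wild-type control mean; points are arrays, bars the group mean and SD (n = 6). Acute phase means are 1.34 to 1.59 in infected arrays of both genotypes, and interferon-stimulated gene means of knockout infected arrays form 2 sets, 0.433 to 0.455 and 2.38 to 2.52.

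Infection in knockout mice raised acute phase and inflammatory genes and lowered bile acid, lipogenic and fatty acid oxidation genes. A2m rose 24.7-fold (log2 4.63 ± 0.51), Cdkn1a 22.1-fold (4.47 ± 0.26) and Cd14 21.8-fold (4.44 ± 0.43). Cyp7a1 fell 36.9-fold (-5.20 ± 0.48), and Hsd3b3 and Hsd3b2, both of the steroid dehydrogenase family, fell 16.8-fold (-4.07 ± 0.45) and 14.2-fold (-3.83 ± 0.18). Ehhadh, the peroxisomal bifunctional enzyme, fell 2.85-fold (-1.51 ± 0.22) and Acot1, an acyl-CoA thioesterase gene, 5.09-fold (-2.35 ± 0.34). Of 22180 genes 3388 were higher and 3800 lower, 727 and 1073 by 2-fold or more, and 14992 did not pass.

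Genes with the greatest rise in knockout mice also included Slc10a6 (23-fold), Saa3 (20.1-fold), Slfn4 (19.2-fold), Ch25h (16.8-fold), whose enzyme makes 25-hydroxycholesterol, and Selp (15.2-fold). Keg1 (20.4-fold), Hykk (log2 -3.74), Cyp3a25 (12.9-fold), Apol7a (12-fold) and Sdr9c7 (11.9-fold) were among those with the greatest fall. Of 28 acute phase genes 26 rose, 0 fell and 2 did not pass, with 28 and 0 adjusted over the list alone (camera adjusted p = 3.39e-22), and Saa2 rose 8.08-fold and Lcn2 6.80-fold, both near the top of the scale after infection. Cytokine and chemokine genes rose in 20 of 27 cases with 1 lower and 6 not past, 22 and 1 adjusted over the list alone (camera adjusted p = 2.49e-12). Ccl3 rose 14-fold, Ccl2 9.99-fold, Cxcl1 7.51-fold, Tnf 2.65-fold, Il1b 2.64-fold and Il6 2.25-fold, and Il18 fell 1.55-fold with all arrays (adjusted p = 0.509 without knockout infected replicates 1 to 3). Of 25 NF-κB feedback genes 22 rose, 0 fell and 3 did not pass, with 23 and 0 adjusted over the list alone (camera adjusted p = 1.94e-18), Irak3 by 13.5-fold. Interferon-stimulated genes rose in 22 of 26 cases with 0 lower and 4 not past, 23 and 0 adjusted over the list alone (camera adjusted p = 2.72e-11, adjusted p = 0.192 with an estimated correlation), Rsad2 by 7.18-fold and Isg15 by 6.03-fold. Their array means were 0.433 to 0.455 in replicates 1 to 3 and 2.38 to 2.52 in replicates 4 to 6. Of 18 glucocorticoid-induced genes 15 rose, 2 fell and 1 did not pass, with 15 and 2 adjusted over the list alone (camera adjusted p = 8.85e-09), Ddit4 by 9.72-fold. Unfolded protein response genes rose in 12 of 23 cases with 2 lower and 9 not past, 13 and 2 adjusted over the list alone (camera adjusted p = 5.09e-05, adjusted p = 0.152 with an estimated correlation), Chac1 by 7.91-fold.

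Metabolic lists fell in knockout mice. Of 31 PPARα target genes 16 fell, 4 rose and 11 did not pass, with 17 and 7 adjusted over the list alone (camera adjusted p = 0.00119, adjusted p = 0.192 with an estimated correlation). Acot3 fell 5.15-fold and Mgll 4.65-fold, and Angptl4 and Pdk4 rose 3.88-fold and 3.36-fold. Mitochondrial fatty acid oxidation genes fell in 15 of 18 cases with 0 higher and 3 not past, 15 and 1 adjusted over the list alone (camera adjusted p = 1.07e-07). Hadh fell 3.32-fold, Acaa2 2.17-fold and the medium-chain dehydrogenase gene Acadm 2.14-fold, while Cpt1a differed by 0.26 ± 0.10 (adjusted p = 0.0524). Peroxisomal genes fell in 16 of 19 cases with 0 higher and 3 not past, 17 and 1 adjusted over the list alone (camera adjusted p = 1.26e-11), Abcd2 by 5.70-fold and Acot4 by 5.17-fold. Of 24 oxidative phosphorylation genes 22 fell, 0 rose and 2 did not pass, with 23 lower adjusted over the list alone (camera adjusted p = 3.44e-09, adjusted p = 0.135 with an estimated correlation), Sdhc by 1.52-fold. Tricarboxylic acid cycle genes fell in 13 of 17 cases with 1 higher and 3 not past, 13 and 1 adjusted over the list alone (camera adjusted p = 0.000143), Idh2 by 2-fold. Lipogenesis genes fell in 14 of 16 cases with 0 higher and 2 not past, 15 lower adjusted over the list alone (camera adjusted p = 2.72e-11), and Srebf1, the lipogenic transcription factor SREBP-1, fell 6.14-fold. Genes of cholesterol synthesis and uptake fell in 18 of 19 cases with 0 higher and 1 not past, 19 lower adjusted over the list alone (camera adjusted p = 5.39e-11, adjusted p = 0.0581 with an estimated correlation), Insig1 by 5.77-fold. Bile acid genes fell in 15 of 17 cases with 1 higher and 1 not past, 15 and 1 adjusted over the list alone (camera adjusted p = 9.09e-10), Akr1d1 by 7.05-fold. Xenobiotic genes fell in 23 of 27 cases with 0 higher and 4 not past, 24 lower adjusted over the list alone (camera adjusted p = 2.72e-11, adjusted p = 0.0744 with an estimated correlation), Nr1i3 by 8.91-fold. Array means of the bile acid list were -2.06 to -2.01 in knockout infected replicates 1 to 3 and -1.35 to -0.926 in replicates 4 to 6, and those of the xenobiotic list -1.75 to -1.33 and -0.742 to -0.419. Clock genes split into 5 higher, 6 lower and 5 not past of 16, with 5 and 6 adjusted over the list alone (camera adjusted p = 0.498), with Dbp down 7-fold and Nfil3 up 4.94-fold.

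Neutrophil markers rose in 19 of 20 cases in knockout mice with 0 lower and 1 not past, 19 and 0 adjusted over the list alone (camera adjusted p = 4.22e-15), S100a8 by 8.98-fold. Monocyte markers rose in 7 of 12 cases with 1 lower and 4 not past, 7 and 1 adjusted over the list alone (camera adjusted p = 0.0031, adjusted p = 0.139 with an estimated correlation), Chil3 by 7.76-fold. Kupffer cell markers fell in 13 of 16 cases with 2 higher and 1 not past, 13 and 2 adjusted over the list alone (camera adjusted p = 8.29e-07, adjusted p = 0.0993 with an estimated correlation). Cd5l fell 5.94-fold. Liver endothelial markers fell in 12 of 16 cases with 2 higher and 2 not past, 12 and 2 adjusted over the list alone (camera adjusted p = 6.94e-07, adjusted p = 0.0273 with an estimated correlation), Clec4g by 7.59-fold. Of 13 negative acute phase and secreted hepatocyte genes 6 fell, 0 rose and 7 did not pass, with 6 lower adjusted over the list alone (camera adjusted p = 0.0114, adjusted p = 0.192 with an estimated correlation and 0.24 without knockout infected replicates 1 to 3), and Igfals fell 4.64-fold. Without knockout infected replicates 1 to 3, a setting chosen after seeing the arrays, 9123 genes were called and 6204 of the 7188 were shared in direction. Effects past the threshold in both settings moved by over 1.5-fold for several named genes. On the log2 scale, those without the replicates were -2.69 for Hsd3b3 (-4.07 with all arrays), -0.73 for Hadh (-1.73), -1.2 for Akr1d1 (-2.82), -0.87 for Ehhadh (-1.51), -2.59 for Apol7a (-3.59), -4.37 for Cyp7a1 (-5.20), -3.58 for Keg1 (-4.35) and -4.71 for Hykk (-3.74). They were 3.88 for A2m (4.63), 1.75 for Chil3 (2.96), 4.70 for Selp (3.93), 4.49 for Ccl3 (3.80), 3.95 for Ccl2 (3.32), 3.80 for Chac1 (2.98), 4.40 for Rsad2 (2.84), 3.39 for Isg15 (2.59), 3.35 for Nfil3 (2.30) and 2.62 for Pdk4 (1.75). Cd5l had -1.82 (-2.57) and Clec4g -2.02 (-2.92). Serpina6 differed by -0.83 ± 0.29 over all arrays (adjusted p = 0.0256) and by 0.11 without those replicates (adjusted p = 0.391).

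Without infection, knockout mice had lower PPARα target and fatty acid oxidation genes and differed in clock genes. Cyp4a14 was 48.1-fold lower (log2 -5.59 ± 0.49) and Vnn1 15-fold lower (-3.91 ± 0.20). Dbp and Per3, clock output and clock genes, were 11.3-fold higher (3.49 ± 0.20) and 8.20-fold higher (3.04 ± 0.19), and Npas2 and Arntl, which form the activating arm of the clock, were 11.2-fold lower (-3.48 ± 0.28) and 6.88-fold lower (-2.78 ± 0.27). Fgf21 was 2.58-fold lower (-1.37 ± 0.28). Of 22180 genes 262 were higher and 473 lower, 39 and 101 by 2-fold or more, and 21445 did not pass. The labels give neither collection time nor feeding per group, so their part in these differences could not be separated from genotype. The same wild-type controls are the baseline for infection in wild type.

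Clock genes were higher in 8 of 16 cases, lower in 4 and not past in 4, with 11 and 4 adjusted over the list alone (camera adjusted p = 9.69e-09). Ciart was 6.76-fold higher, Tef 4.62-fold and Nr1d2 3.93-fold. Usp2 and Wee1, both clock-controlled, were 6.85-fold and 4.84-fold higher, and Per1 2.77-fold. PPARα target genes were lower in 11 of 31 cases, higher in 1 and not past in 19, with 13 and 2 adjusted over the list alone (camera adjusted p = 8.18e-12). Cyp4a31 was 5.38-fold lower and Angptl4 2.16-fold, and Acot3 1.74-fold higher, while Pdk4 (-0.84 ± 0.38, adjusted p = 0.321), Ehhadh (-0.08 ± 0.22, adjusted p = 0.948), Acot1 (1.09 ± 0.34, adjusted p = 0.0787) and Cpt1a (0.23 ± 0.10, adjusted p = 0.327) did not pass. Of 18 mitochondrial fatty acid oxidation genes 8 were lower, 0 higher and 10 not past, with 8 lower adjusted over the list alone (camera adjusted p = 7.38e-12). The carnitine-acylcarnitine translocase gene Slc25a20 was 2.09-fold lower, Etfdh 2.05-fold and Cpt2 1.87-fold. Peroxisomal genes were lower in 5 of 19 cases, higher in 2 and not past in 12, with 6 and 2 adjusted over the list alone (camera adjusted p = 0.000547, adjusted p = 0.137 with an estimated correlation), Abcd2 by 4.29-fold. Of 17 lipid droplet and lipolysis genes 3 were lower, 1 higher and 13 not past, with 7 and 3 adjusted over the list alone (camera adjusted p = 0.00295, adjusted p = 0.137 with an estimated correlation). Fitm1 was 4.45-fold lower and Plin5 3.54-fold. Of 22 cell cycle genes 9 were lower, 0 higher and 13 not past, with 12 and 1 adjusted over the list alone (camera adjusted p = 4.17e-13), including Cdkn1a, an inhibitor of the cycle, 3.88-fold, Ccna2 2.65-fold and Ccnb2 2.37-fold. Acute phase genes were lower in 3 of 28 cases, higher in 0 and not past in 25, with 5 lower adjusted over the list alone (camera adjusted p = 0.00334, adjusted p = 0.686 with an estimated correlation), Lrg1 by 1.66-fold. Adipocyte markers passed as a list with 0 of 5 members past the threshold and 4 lower adjusted over the list alone (camera adjusted p = 0.00198, adjusted p = 0.27 with an estimated correlation). Their array means overlapped, at -0.834 to 1.06 in wild-type controls (SD 0.832) and -1.05 to -0.759 in knockout controls (SD 0.134). The difference thus rests on wild-type control arrays with high values. Other genes with a large difference were Lnx1 (3.61-fold higher), Cyp3a16 (13.9-fold lower), the sulfotransferase gene Sult2a1 (8.51-fold lower) and A1bg (7.53-fold lower). Il1b was 1.71-fold lower. Fitted on the 12 uninfected arrays alone, 988 genes were higher and 1278 lower, and against a 1.2-fold change as the null 51 were higher and 142 lower.

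With infection, knockout livers had lower PPARα target, fatty acid oxidation, lipid droplet, NF-κB feedback and cytokine genes than wild-type livers. Cyp4a14 was 40.9-fold lower (log2 -5.35 ± 0.49), Rab30, a small GTPase gene, 25-fold (-4.64 ± 0.21), Vnn1 19.3-fold (-4.27 ± 0.20) and Pdk4 8.19-fold (-3.03 ± 0.38). Ehhadh was 3-fold lower (-1.59 ± 0.22) and Fgf21 2.45-fold lower (-1.29 ± 0.28). The chemokine genes Ccl2 and Cxcl1 were 3.16-fold (-1.66 ± 0.26) and 2.49-fold lower (-1.31 ± 0.28). Of 22180 genes 725 were higher and 820 lower, 38 and 167 by 2-fold or more, and 20635 did not pass. Fitted on the 12 infected arrays alone, 58 genes were higher and 252 lower, with array weights 271 and 427, and 7 of 100 regroupings of the arrays, the real one included, called at least 1545 genes.

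PPARα target genes were lower in 23 of 31 cases, higher in 0 and not past in 8, with 27 lower adjusted over the list alone (camera adjusted p = 2.52e-39). Of 18 mitochondrial fatty acid oxidation genes 14 were lower, 0 higher and 4 not past, with 16 lower adjusted over the list alone (camera adjusted p = 2.4e-26). Eci2 was 2.71-fold lower, Slc25a20 2.48-fold and Etfdh 2.44-fold, and Cpt1a differed by -0.11 ± 0.10 (adjusted p = 0.583). Of 19 peroxisomal genes 12 were lower, 1 higher and 6 not past, with 13 and 2 adjusted over the list alone (camera adjusted p = 3.5e-17). Decr2 was 4.11-fold lower, Acaa1b 3.40-fold and Acot3 3.04-fold. Of 17 lipid droplet genes 8 were lower, 1 higher and 8 not past, with 9 and 2 adjusted over the list alone (camera adjusted p = 1.01e-07), Cidec by 4.16-fold and Plin4 by 2.92-fold. Lipogenesis genes were lower in 6 of 16 cases, higher in 0 and not past in 10, with 7 lower adjusted over the list alone (camera adjusted p = 2.96e-05, adjusted p = 0.0956 with an estimated correlation), Fads2 by 2.85-fold and Srebf1 by 2.76-fold. Xenobiotic genes were lower in 2 of 27 cases with 0 higher and 25 not past, 2 lower adjusted over the list alone (camera adjusted p = 0.00162, adjusted p = 0.578 with an estimated correlation). Oxidative phosphorylation genes were lower in 1 of 24 cases with 0 higher and 23 not past, 7 lower adjusted over the list alone (camera adjusted p = 0.000179, adjusted p = 0.554 with an estimated correlation).

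Of 25 NF-κB feedback and inflammasome genes 14 were lower, 0 higher and 11 not past, with 19 and 1 adjusted over the list alone (camera adjusted p = 4.2e-16). The inflammasome caspase gene Casp4 was 3.48-fold lower, Sele, which encodes E-selectin, 3.08-fold and Ptgs2, the inducible cyclooxygenase, 2.58-fold. Without knockout infected replicates 1 to 3, 10 of the 25 were lower, Sele differed by -0.61 (adjusted p = 0.0793, -1.62 with all arrays) and Ptgs2 by -0.77 (adjusted p = 0.0287, -1.37 with all arrays). Of 27 cytokine and chemokine genes 12 were lower, 1 higher and 14 not past, with 16 and 1 adjusted over the list alone (camera adjusted p = 6.97e-11), and Cxcl10 was 3.66-fold lower, Csf3 2.78-fold and Tnf 1.45-fold. With knockout infected replicates 1 to 3 left out, 6 of these 27 were lower and 0 higher (camera adjusted p = 0.00202, adjusted p = 0.218 with an estimated correlation). Il1b (-0.11 ± 0.17, adjusted p = 0.766), Saa2 (0.04 ± 0.48, adjusted p = 0.978) and Lcn2 (-0.08 ± 0.34, adjusted p = 0.923) did not pass, where Saa2 and Lcn2 of infected mice lay near the top of the scale. Interferon-stimulated genes were lower in 7 of 26 cases, higher in 0 and not past in 19, with 17 lower adjusted over the list alone (camera adjusted p = 1.83e-10, adjusted p = 0.418 with an estimated correlation). Without knockout infected replicates 1 to 3 their direction turned, with 2 higher and 1 lower of 26 (camera adjusted p = 0.00735, adjusted p = 0.536 with an estimated correlation). Mx1 was 3.56-fold lower over all arrays and differed by -0.03 (adjusted p = 0.967) without them, and Cxcl10 by -0.12 (adjusted p = 0.851). The xenobiotic list turned without them to a median of 0.13, with 0 higher and 0 lower of 27 (camera adjusted p = 0.0132, adjusted p = 0.592 with an estimated correlation), and for oxidative phosphorylation the list call ended (camera adjusted p = 0.701). Both measured erythroid markers were lower, 2 of 2 adjusted over the list alone (camera adjusted p = 0.000981), Slc4a1 by 1.64-fold. Without knockout infected replicates 1 to 3, 1 of the 2 erythroid markers was lower (camera adjusted p = 0.0132, adjusted p = 0.0659 with an estimated correlation). Acute phase genes were higher in 0, lower in 0 and not past in 28 of 28 cases, 0 and 0 adjusted over the list alone (camera adjusted p = 0.784), and clock genes higher in 0 and lower in 0 of 16, 0 and 0 adjusted over the list alone (camera adjusted p = 0.603). With replicates 4 to 6 of the knockout infected group alone 3 clock genes were higher and 1 lower (camera adjusted p = 0.294), and with replicates 1 to 3 alone 2 were higher and 5 lower (camera adjusted p = 0.165). Of 16 liver endothelial markers 4 were higher, 2 lower and 10 not past, with 6 and 3 adjusted over the list alone (camera adjusted p = 0.111), and Oit3 was 1.72-fold higher and Clec4g 2.16-fold lower, neither past without replicates 1 to 3 (adjusted p = 0.258 and 0.56). Higher in knockout were Cxcl14 (3.56-fold), Lnx1 (3.37-fold), Rpl3 (2.81-fold), Trmt1l (2.75-fold) and Papola (2.24-fold), of which Rpl3 differed by -0.33 (adjusted p = 0.395) at its probe set with the lowest mean. Retsat (5.81-fold), Serpina7 (5.15-fold), Ifi208 (8.55-fold) and Sult2a1 (6.05-fold) were lower.

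Without knockout infected replicates 1 to 3, 41 named genes lost their call, among them Cxcl10, Mx1, Sele, Oit3, Clec4g and Tnf (-0.58, adjusted p = 0.0628, and -0.53 with all arrays), and 440 of 1545 genes kept their call and direction. Differences past the threshold in both settings were -2.16 without them and -3.03 with all arrays for Pdk4, -0.95 and -1.59 for Ehhadh, -1.03 and -1.66 for Ccl2, -1.81 and -2.54 for Retsat, -0.92 and -1.77 for Acaa1b, -0.66 and -1.51 for Fads2 and 1.2 and 1.83 for Cxcl14. That setting, chosen after seeing the arrays, called 352 genes higher and 733 lower. Leaving out 1 array moved the number of genes higher to 407 (wild-type infected replicate 3), 426 (wild-type infected replicate 6), 301, 319 and 332 (knockout infected replicates 1, 2 and 3) or 1549, 1488 and 1367 (knockout infected replicates 4, 5 and 6), and the number lower to 525, 536 and 1256 without knockout infected replicates 1, 3 and 5.

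The infection response of the genotypes differed in clock genes, PPARα target genes and NF-κB feedback genes, among other lists. With an estimated correlation and without knockout infected replicates 1 to 3, the clock call held (adjusted p = 0.0137) and those of PPARα targets (adjusted p = 0.17) and NF-κB feedback (adjusted p = 0.0541) did not. With the preset correlation the PPARα and NF-κB calls held there (medians -0.425 and -0.349, camera adjusted p = 5.33e-10 and 3.15e-06). Relative to wild-type controls, clock means were 0.555 in wild-type infected, 0.641 in knockout control and 0.437 in knockout infected arrays. By group means the wild-type controls thus stood apart. By array, knockout infected replicates 1 to 3 ran from -0.00239 to 0.446, which reaches the wild-type control range of -0.0899 to 0.148. Replicates 4 to 6 ran from 0.621 to 0.662. The list mean also nets members that move in opposite directions. The clock interaction contains the difference between uninfected genotypes. Collection time or feeding cannot be told apart from genotype there. The interaction, the response in knockout minus that in wild type, was -3.41 ± 0.28 for Dbp (10.7-fold), -2.56 ± 0.27 for Per3 and -3.20 ± 0.29 for Rab30, and 3.02 ± 0.39 for Npas2. Pdk4 rose 15.3-fold with infection in wild type and 3.36-fold in knockout, an interaction of -2.19 ± 0.54 (adjusted p = 0.0221). Acot3, a peroxisomal acyl-CoA thioesterase gene, had an interaction of -2.41 ± 0.27, Acot1 of -1.84 ± 0.47 and Ehhadh of -1.51 ± 0.31. Of 22180 genes 388 had a higher response in knockout and 360 a lower one, 115 and 120 by 2-fold or more, and 21432 did not pass.

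**Figure D4:**
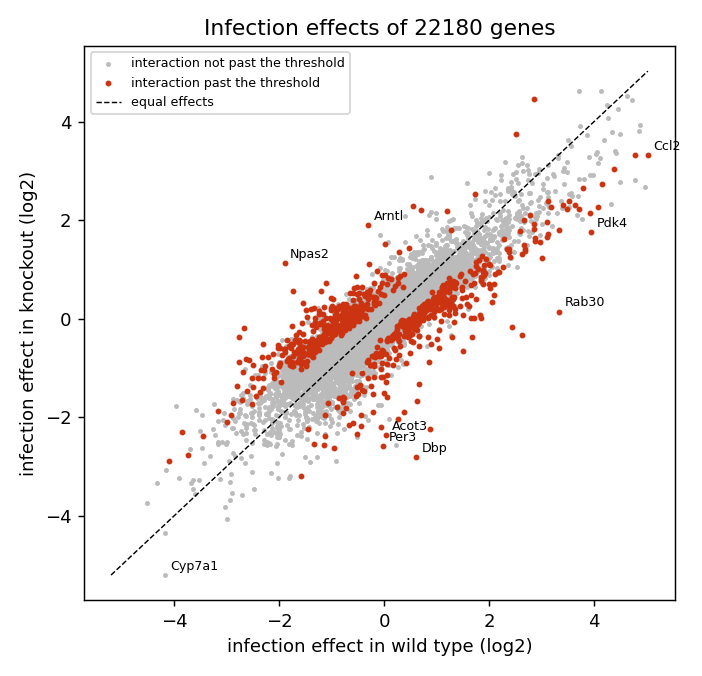
Infection effect (log2) of each of 22180 genes in wild type (x axis) and knockout (y axis); red points have an interaction past the threshold and the dashed line marks equal effects. Dbp and Per3 lie below the line, Npas2 and Arntl above it.

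Clock genes had a lower response in 8 of 16 cases, a higher one in 3 and no call in 5, with 9 and 3 adjusted over the list alone (camera adjusted p = 8.06e-07). Ciart had -2.61 ± 0.40, Arntl 2.21 ± 0.38 and Wee1 -2.30 ± 0.34, and Usp2 -3.11 ± 0.29. PPARα target genes had a lower response in 9 of 31 cases, a higher one in 0 and no call in 22, with 15 lower adjusted over the list alone (camera adjusted p = 9.83e-11). Peroxisomal genes did so in 7 of 19 cases with 0 higher and 12 not past, 10 and 2 adjusted over the list alone (camera adjusted p = 8.06e-07), and mitochondrial fatty acid oxidation genes in 2 of 18 with 0 higher and 16 not past, 6 lower adjusted over the list alone (camera adjusted p = 8.06e-07, adjusted p = 0.0711 with an estimated correlation). NF-κB feedback genes had a lower response in 9 of 25 cases, a higher one in 0 and no call in 16, with 15 lower adjusted over the list alone (camera adjusted p = 4.28e-12). Tnfaip3 had -1.34 ± 0.30 and Sele -1.79 ± 0.46. Cytokine and chemokine genes had a lower response in 8 of 27 cases, a higher one in 0 and no call in 19, with 15 and 1 adjusted over the list alone (camera adjusted p = 8.84e-09, adjusted p = 0.0711 with an estimated correlation). Ccl2 had -1.71 ± 0.36, Csf3 -1.40 ± 0.24 and Tnf -0.97 ± 0.21. Cell cycle genes had a higher response in 6 of 22 cases, a lower one in 0 and no call in 16, with 10 higher adjusted over the list alone (camera adjusted p = 7.15e-07, adjusted p = 0.114 with an estimated correlation), Ccnb2 with 1.60 ± 0.31. Relative to wild-type controls, cell cycle means were -0.33 in wild-type infected, -0.572 in knockout control and -0.348 in knockout infected arrays. Interferon-stimulated genes had a lower response in 2 of 26 cases with 0 higher and 24 not past, 2 lower adjusted over the list alone (camera adjusted p = 5.59e-05, adjusted p = 0.551 with an estimated correlation), and without knockout infected replicates 1 to 3 a higher one (4 higher and 1 lower, camera adjusted p = 2.21e-05, adjusted p = 0.245 with an estimated correlation). Cyp2b10 (2.29 ± 0.43), Foxq1 (1.89 ± 0.26), Slc45a3 (1.87 ± 0.29), Tubb2a (1.83 ± 0.32), Ect2 (1.81 ± 0.31) and Spon2 (1.79 ± 0.20) had a higher response in knockout, and Rgs16 (-2.96 ± 0.61) a lower one. Without those replicates 390 of 748 genes kept their call and direction, and 5 of 25 NF-κB feedback and 4 of 27 cytokine genes had a lower response. Pdk4 (-1.32, adjusted p = 0.0964), Acot1 (-1.42, 0.0977), Sele (-0.78, 0.0961) and Tnfaip3 (-0.88, 0.0676) did not pass with the fewer arrays. Past the threshold in both settings were Ehhadh (-0.87), Ccl2 (-1.07), Cyp2b10 (1.64), Usp2 (-2.52) and Rgs16 (-2.30). Leaving out knockout infected replicate 4, 5 or 6 moved the number of genes higher to 798, 778 or 663, and leaving out replicate 5 moved the number lower to 562.

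Across genes, infection effects of the genotypes correlated at Pearson 0.867 and Spearman 0.761 with a slope of 0.73 (jackknife SE 0.0879) for knockout on wild type, where genes are not independent replicates. The slope was 0.897 with knockout infected replicates 4 to 6 alone and 0.564 with replicates 1 to 3 alone. Of 5848 genes called in both, 5808 changed in the same direction. The infection contrasts of the genotypes share no arrays.

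Genes lower after infection in wild type and lower in uninfected knockout mice numbered 312, against 107 expected of independent lists of 5025 and 473 genes. The number was 728 with array weights, 856 with the compared groups alone, 605 without knockout infected replicates 1 to 3, 571 without replicates 4 to 6, 183 at a threshold of 0.01 and 75 against a 1.2-fold change. Both comparisons use the wild-type controls. With the 6 controls split so that each comparison used other arrays, the 20 splits gave 127 to 204 genes (median 157), against 41.5 to 64.7 expected of independent lists. The split removes noise of shared arrays, but not a trait common to all 6 controls, such as collection time or feeding. The expected numbers also treat all genes as equally likely to be called. The excess therefore does not show that the knockout resembles infection.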

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

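All tests of the 3 patterns below were chosen after the result was seen, except the substrain test, and the counts of regrouped arrays or shuffled residuals were described after the fits as well.

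Knockout infected replicates 1 to 3 lay apart from replicates 4 to 6, with interferon-stimulated gene means of 0.433 to 0.455 and 2.38 to 2.52, and wild-type infected arrays parted less, by the same numbers and in the opposite direction (16 to 25 and -8.03 to 6.28 on the second principal component). A mislabelled uninfected mouse is argued against, since replicates 1 to 3 lay beyond all 12 control arrays on 90.9% of the lists called for infection in wild type (20 of 22), a test that replaced a first one on acute phase genes (gap 0.882, first bound 1) after that value was seen. A mislabelled wild-type mouse is argued against by Cyp4a14 and Vnn1, whose lowest wild-type array lay at least 1.82 above the highest knockout infected array (log2). Markers of 2 other cell types were higher and of 2 lower in replicates 1 to 3, while a lower hepatocyte share alone was predicted to move them 1 way. These markers also moved with infection in wild type, for instance endothelial markers by a mean of -1.24 and cholangiocyte markers by 0.507. They can thus follow the strength of the response, and a lower hepatocyte share could not be decided. No biological explanation was tested, RNA quality and a separate infection or array day were not testable from the labels, and these may each contribute.

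Clock genes differed between uninfected genotypes. Array scaling is argued against, since 8 members were higher and 4 lower under each of 3 scalings (smaller side 4). A loss of PPARα that acts alike with and without infection is argued against, since the median difference, each member turned to its direction without infection, was 1.35 without and 0.157 with infection, a ratio of 0.117 (0.164 with knockout infected replicates 4 to 6 alone and -0.00558 with replicates 1 to 3 alone). With 12 members called, a difference in collection time or feeding between the uninfected groups cannot be told apart from genotype, since the labels give neither per group. A genotype effect present without infection alone stays open as a hypothesis.

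Of the genes called between genotypes, 126 differed in 1 direction with and without infection, 23 higher and 103 lower in knockout. Loss of PPARα may account for part, since 11 of 31 PPARα target genes were among those lower (one-sided Fisher exact p = 9.8e-19). DNA around Ppara carried along with the deletion is argued against as the whole source, since its neighbours made up 3.97% of these genes, yet it may account for some neighbours, as 5 of 200 were among them against 1.14 expected (Tob2, Ndufa6, Cyb5r3, Rabl2 and Abcd2, one-sided Fisher exact p = 0.00579). Abcd2 is also a member of the peroxisomal list, which was lower in knockout, so loss of PPARα and carried-along DNA cannot be told apart for it. Of the substrain genes Wdfy1, Ide and Entpd4, 0 were called in both comparisons, which met the bound set beforehand against a substrain difference, but that bound needed all 3 genes and Entpd4 was not analysed here, so its reading was changed after the result and a substrain background cannot be told apart. Wdfy1 was 0.81 ± 0.08 without and 0.21 ± 0.08 with infection (adjusted p = 8.63e-08 and 0.0932). Nnt, known beforehand to differ between substrains, was higher in both, at 1.05 ± 0.10 and 0.89 ± 0.10 (adjusted p = 9.06e-08 and 1.52e-06). That offset goes with a substrain difference, but Nnt was not part of the test set beforehand and is a single gene.

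Regrouping the arrays of each comparison into 100 splits, the real one included, tested whether chance could give as many called genes. For infection in wild type 1 split reached the real 9365 (highest other 4971), for infection in knockout 1 reached 7188 (3607), and for genotype without infection 1 reached 735 (40), so chance was excluded for these. For the interaction 3 of the 100 splits reached 748, under the share of 0.05 at which chance stays open, but with 4743 in the highest other split. For genotype with infection 7 splits reached 1545, so chance was not excluded for that count. Its highest other split, 4469, and the highest other draw of the interaction lay several times above the real counts, which points to a structure among the arrays.

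Infection effects differed between genotypes by the interaction test in 388 genes higher and 360 lower in knockout. The interaction was 3.02 for Npas2, 2.29 for Cyp2b10, 2.21 for Arntl, 1.89 for Foxq1, 1.87 for Slc45a3, 1.83 for Tubb2a, 1.81 for Ect2 and 1.79 for Spon2. It was -3.41 for Dbp, -3.20 for Rab30, -3.11 for Usp2, -2.96 for Rgs16, -2.61 for Ciart, -2.56 for Per3, -2.41 for Acot3 and -2.30 for Wee1. For Ppara it was -0.97, for Ehhadh -1.51, for Pdk4 -2.19, for Acot1 -1.84 and for Tnf -0.97.

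By list, the interaction had a camera adjusted p of 9.83e-11 for PPARα target genes, 8.06e-07 for mitochondrial and for peroxisomal fatty acid oxidation and for the clock, 0.0253 for lipogenesis and for acute phase proteins, 0.0205 for cholesterol synthesis and uptake, 6.46e-06 for xenobiotic metabolism, 0.0459 for lipid droplets and 0.00127 for oxidative phosphorylation. It was 8.84e-09 for cytokines and chemokines, 4.28e-12 for NF-κB feedback, 5.59e-05 for interferon-stimulated genes, 7.15e-07 for the cell cycle, and 0.0296, 0.0119, 0.0278 and 0.00597 for Kupffer cell, liver endothelial, stellate cell and erythroid markers. With an estimated correlation 5 of these 18 calls held. Interferon-stimulated genes turned without knockout infected replicates 1 to 3, from a median of -0.58 to 0.31 (adjusted p = 2.21e-05, 0.245 with an estimated correlation). Without knockout infected replicates 1 to 3 the list median was -0.18 for lipogenesis (adjusted p = 0.221, -0.24 with all arrays), 0.16 for cholesterol synthesis (0.699, 0.49), -0.09 for xenobiotic metabolism (0.588, -0.69) and -0.06 for oxidative phosphorylation (0.516, -0.14). It was 0.09 for acute phase proteins (0.138, 0.13), -0.15 for Kupffer cell markers (0.141, -0.15) and 0.06 for liver endothelial markers (0.163, 0.34).

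Single arrays far from the other 5 of their group were found in 14 of 152 list means and 5 of 84 gene levels, where chance marks about 1 in 20. Relative to the wild-type control mean (log2), knockout infected arrays stood apart for gluconeogenesis (replicate 2, 0.0169), cholesterol synthesis and uptake (replicate 1, -0.458), oxidative stress (replicate 3, 0.0439), adipocyte markers (replicate 4, 0.791) and sex markers (replicate 6, -1.04). Wild-type infected replicate 2 stood apart for oxidative phosphorylation (-0.0708) and liver endothelial markers (-1.07). Wild-type controls did for glycolysis (replicate 3, 0.0872), nuclear receptors (replicate 4, -0.0794), neutrophil markers (replicate 3, 0.228) and Kupffer cell markers (replicate 6, -0.239). Knockout controls did for xenobiotic metabolism (replicate 5, 0.0654), Kupffer cell markers (replicate 2, 0.667) and T, B and NK cell markers (replicate 4, -0.0486). By gene level, Pdk4 read 8.61 in knockout control replicate 1, Saa2 12.8 in wild-type infected replicate 2 and Alb 13.1 in wild-type control replicate 4. Xist read 9.54 in wild-type infected replicate 2 and 5.98 in knockout infected replicate 6, against 9.94 to 10.3 in the other knockout infected arrays.

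Of 17824 probe sets without a single gene name, 2430 were higher and 1293 lower after infection in wild type.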

How the results depend on the processing

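The settings with knockout infected replicates 4 to 6 alone and 1 to 3 alone were chosen after the arrays were seen. The cause of each difference below was not tested, except where fewer arrays or a stricter threshold gives it by construction. All 17 counts and summary values stayed within 1.5 times their main value with the replicate block, quantile normalization again, arrays centred on their median, without dim genes, with the mean or lowest probe set and with eBayes trend and robust. With the replicate block, 4222 genes were higher and 4943 lower for infection in wild type, 3285 and 3708 in knockout, 224 and 428 for genotype without infection, 607 and 674 with infection and 317 and 273 for the interaction. After each group mean was subtracted, 0 of 36 correlations between arrays of like number were above 0.1. Between the infected groups these correlations averaged -0.138 (lowest -0.366), against 0.0277 for other numbers. No scaling moved the median of all genes by over 0.1.

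With array weights, whose estimation stopped before convergence, 872 genes were higher and 1134 lower for genotype without infection and 271 and 427 with infection, and the overlap of lower genes was 728. With the compared groups alone these were 988 and 1278, 58 and 252, and 856. At a threshold of 0.01 they were 124 and 292, 183 and 380, and 183, the interaction had 109 and 129, and 11 lists were called for it. Against a 1.2-fold change, infection in wild type had 2116 and 3194, in knockout 1584 and 2176, genotype without infection 51 and 142, with infection 40 and 198, the interaction 63 and 80, and the overlap was 75. With the wild-type controls split, the median overlap was 157.

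With replicates 4 to 6 of the knockout infected group alone, genotype without infection had 589 and 897, genotype with infection 352 higher, and the overlap was 605. With replicates 1 to 3 alone these were 540 and 858, 4352 higher and 2631 lower, and 571, the interaction had 3728 and 2124, 17 lists were called for genotype with infection, and infection effects correlated at 0.655 between genotypes. With replicates 4 to 6 alone, lists turned direction for genotype with infection in cholesterol synthesis and xenobiotic metabolism (camera adjusted p = 0.0132 for each), amino acid catabolism (0.000603) and interferon-stimulated genes (0.00735), and for the interaction in amino acid catabolism (0.00994) and interferon-stimulated genes (2.21e-05). Cholesterol synthesis was not called with all arrays for genotype with infection, nor amino acid catabolism in either comparison, so these were new calls. With an estimated correlation none of these calls held, at 0.536, 0.592, 0.375 and 0.536, and 0.466 and 0.245. With these replicates alone and an estimated correlation, calls also ended for infection in knockout in mitochondrial fatty acid oxidation (0.17, median log2 -0.572), lipogenesis (0.0784, -1.14), bile acids (0.11, -0.996), the tricarboxylic acid cycle (0.17, -0.379), acute phase proteins (0.0669, 1.18), neutrophil markers (0.11, 1.51) and endothelial markers (0.0536, -1.41). With the preset correlation all of these stayed called with these replicates alone (camera adjusted p of 0.00371 or less). For genotype without infection, calls ended in PPARα targets (0.141, median -0.287), mitochondrial fatty acid oxidation (0.0932, -0.216) and the cell cycle (0.0932, -0.393). That comparison does not use the removed arrays, so its medians did not change, only the estimates of spread and correlation. Calls also ended for genotype with infection in cytokines (0.218, median -0.165) and erythroid markers (0.0659, -0.442). For the interaction they ended in PPARα targets (0.17, median -0.425), peroxisomal genes (0.17, -0.254), erythroid markers (0.17, -0.438) and NF-κB feedback (0.0541, -0.349). Serpina6 turned to 0.11 for infection in knockout. Rpl3 turned to -0.33 for genotype with infection at its probe set with the lowest mean.

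Lists called with an estimated correlation numbered 5 of 22 for infection in wild type, 12 of 24 in knockout, 4 of 11 for genotype without infection, 7 of 11 with infection and 5 of 18 for the interaction. With fry they were 34 for infection in wild type, 7 for genotype without infection and 8 for the interaction.

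With each array left out in turn, infection in wild type had 3970 to 4440 higher and 4782 to 5142 lower, infection in knockout 3138 to 3556 and 3483 to 4179, genotype without infection 178 to 286 and 375 to 511, genotype with infection 301 to 1549 and 525 to 1256, and the interaction 262 to 798 and 254 to 562. Genes higher for genotype with infection numbered 407 and 426 without wild-type infected replicates 3 and 6, 301, 319, 332, 1549, 1488 and 1367 without knockout infected replicates 1, 2, 3, 4, 5 and 6, and genes lower 525, 536 and 1256 without replicates 1, 3 and 5. For the interaction 798, 778 and 663 were higher without knockout infected replicates 4, 5 and 6 and 562 lower without replicate 5. Genes higher by 2-fold or more for genotype with infection (main 38) numbered 24 and 20 without knockout infected replicates 1 and 3 and 99, 101 and 87 without replicates 4, 5 and 6, and genes lower (main 167) 256, 260 and 254 without the latter. For the interaction (main 115 and 120) they were 213, 214 and 194 higher, and 190 lower without replicate 5. Lists called ranged over 20 to 23, 23 to 25, 10 to 13, 11 to 14 and 15 to 19, the correlation of infection effects over 0.834 to 0.889 (jackknife SE 0.061) and the overlap over 250 to 340. Of 22180 genes 5235 were dim, and signal near background limits folds there.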

Other observations

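Of 5 ketogenesis genes, 2 were lower and 0 higher between infected genotypes adjusted over the list alone, and 5 did not pass over all genes (camera adjusted p = 0.111). Their array means were -0.614 to -0.26 in knockout infected replicates 1 to 3, 0.276 to 0.462 in replicates 4 to 6 and 0.209 to 0.387 in wild-type infected arrays. Lipoprotein genes fell in 8 of 20 cases with infection in knockout, with 1 higher and 11 not past, and 8 and 1 adjusted over the list alone (camera adjusted p = 0.00831, adjusted p = 0.0993 with an estimated correlation and 0.146 without knockout infected replicates 1 to 3), and in 11 of 20 in wild type with 1 higher and 8 not past, 12 and 1 adjusted over the list alone (camera adjusted p = 0.0563). Coagulation genes fell in 12 of 22 cases in wild type with 5 higher and 5 not past, 13 and 5 adjusted over the list alone (camera adjusted p = 0.553), and in 11 in knockout with 5 higher and 6 not past, 11 and 6 adjusted over the list alone (camera adjusted p = 0.14). Gluconeogenesis genes rose in 6 of 13 cases in wild type with 3 lower and 4 not past, 6 and 4 adjusted over the list alone (camera adjusted p = 0.399), and ketogenesis genes in 2 of 5 with 2 lower and 1 not past, 2 and 3 adjusted over the list alone (camera adjusted p = 0.716).

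Stellate cell markers fell in 7 of 16 cases with infection in wild type, with 1 higher and 8 not past, and 9 and 1 adjusted over the list alone (camera adjusted p = 0.03, adjusted p = 0.245 with an estimated correlation). Cholangiocyte markers rose in 4 of 9 cases with 1 lower and 4 not past, 4 and 1 adjusted over the list alone (camera adjusted p = 0.164). T, B and NK cell markers rose in 4 of 18 cases with 3 lower and 11 not past, 4 and 3 adjusted over the list alone (camera adjusted p = 0.48), and pancreatic acinar markers in 3 of 12 with 0 lower and 9 not past, 3 and 0 adjusted over the list alone (camera adjusted p = 0.263). Xist read 5.98 in knockout infected replicate 6, where the Y-linked genes Kdm5d, Uty and Eif2s3y read 2.44, 1.79 and 2.37, within the range of the other arrays.

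Without infection, a few lists passed in knockout against wild type with few members past the threshold. Cholesterol synthesis genes were lower in 1 of 19 cases with 0 higher and 18 not past, 1 and 0 adjusted over the list alone (camera adjusted p = 0.00198, adjusted p = 0.668 with an estimated correlation). Xenobiotic genes were higher in 2 of 27 cases with 1 lower and 24 not past, 6 and 2 adjusted over the list alone (camera adjusted p = 0.00706, adjusted p = 0.711 with an estimated correlation). T, B and NK cell markers were higher in 1 of 18 cases with 0 lower and 17 not past, 2 and 0 adjusted over the list alone (camera adjusted p = 0.0433, adjusted p = 0.3 with an estimated correlation). Without knockout infected replicates 1 to 3, which this comparison does not use, the camera adjusted p was 0.0544 with the same median of 0.09, since only the estimate of the spread changed.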
